A study of Homo sapiens with 4 samples.

How the data were processed

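The series measured mRNA in human THP-1 cells, an established monocytic leukaemia line. Per the labels' protocols, the cells were turned into macrophages with 100 ng/mL of the phorbol ester PMA for 2 days. After 72 hours without PMA a 24 hour exposure to IL-4 and IL-13 at 20 ng/mL polarised them to the M2 state. The cells then received an siRNA against the long noncoding RNA lnc-M2 or a control siRNA. Each group has 2 samples, and each sample was hybridised to 1 Agilent array in 1 colour (Cy3). The series' design text calls the groups independent without saying whether samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

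The deposited value table holds normalized log2 intensity for 41093 features on the 4 arrays. Arrays were read with Agilent Feature Extraction version 10.7, per the submitters' processing notes. The later normalization, any flags and the array's annotation are not given in the sources used here. In the deposited table the sorted log2 values of the arrays differed by at most 0.000935 at any rank and every array had a median of 6.83, which is the shape that quantile normalization leaves. Such a table cannot show a shift of all transcripts together. Scanner files with background signals, detection flags and saturation flags were not used here. The number of arrays limits the precision, and no counting depth applies.

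A second deposited table holds 2 lists of probes that the authors selected, with their log2 values. One list sets the knockdown array of replicate 1 against the control array of replicate 1, and the other does so for replicate 2. Its values were identical to those of the value table. Each listed probe was at least 2-fold apart within its pair. Probes with such a difference that were not listed reached at most 4.20 on the log2 scale on the brighter array, while listed probes went down to 3.19. The 2 ranges overlap, so a plain brightness cut does not separate them, and no header or label states the further criterion.

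Features were addressed by probe identifier. Neither deposited table pairs a probe with a gene, and 0 of the 41000 probe identifiers occur in the RefSeq gene table of assembly GRCh38.p14 used for names. The 36 gene lists and the gene-level rules fixed before the data were examined could therefore not be applied, and no pathway or cell type statement is made. The rule for named genes asked for the largest changes past the threshold with non-overlapping groups. It was applied to probes, and the 2 probes with the largest rise and the 2 with the largest fall are named.

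The 93 control features were set apart by their names. Of the 41000 remaining probes, the lower 40% by the mean over all 4 arrays (at or below 5.73 on the log2 scale) were left out as dim, which left 24600 tested probes. The deposited log2 values were fitted with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes) with group as the only term. The contrast was lnc-M2 siRNA minus control siRNA, two-sided, with 2 residual degrees of freedom and 4.50 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the tested probes, with a threshold of 0.05. A test on single probes by exact permutation could not go below p = 0.333 with 2 arrays against 2.

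Array pairs were described by the number of probes at least 2-fold apart. Differences were also compared between pairs that share no array. The fit was tested on simulated data with the means of the 24600 tested probes, of which 200 were changed. Variances were drawn at random from the prior that limma fitted, without regard to brightness, and the noise was normal. The fit recovered 32.8% of probes changed 1.5-fold, 86.6% of those changed 2-fold and 98.5% of those changed 4-fold. It made 6 false calls among 151, and 0 calls when no probe was changed. Such data follow the model that limma assumes. In the real arrays the median SD within groups fell from 0.106 to 0.066 with brightness, so the false calls there are not known from the simulation.

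Alternatives set before the data were examined were another quantile normalization, median centring, no filter, a filter on the lower 60%, a trended robust prior, the replicate number as a block, leaving out each array, an adjusted p of 0.1 and a minimum of 2-fold. The counts of 2-fold probes per pair of arrays and the comparison of pairs that share no array were chosen after the data were seen. Cyclic loess normalization and a fit that kept control features were added after the data were seen. Figures were drawn with matplotlib version 3.10.9.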

Results

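The data set asked how the mRNA profile of M2-polarised THP-1 macrophages differs after siRNA against lnc-M2. It held 4 arrays, with 2 samples treated with lnc-M2 siRNA and 2 with control siRNA. Each array gave normalized log2 intensities for 41000 probes and 93 control features. The median intensity was 6.83 on every array, with quartiles of 3.94 and 9.70. Across the 24600 tested probes, the 2 knockdown arrays correlated at r = 0.996 and the 2 control arrays at r = 0.997. The median SD between replicates was 0.076 on the log2 scale in the knockdown group and 0.059 in the control group. In the 16400 dim probes the corresponding medians were 0.150 and 0.141. The arrays share practically 1 set of sorted values, assigned to different probes on each array.

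The targeted transcript could not be read out. The labels give lnc-M2 neither a sequence nor a locus, and no table used here pairs a probe with it. The extent of the knockdown was therefore not measured in these files. Genes behind the probes are likewise not named, because the deposited tables hold probe identifiers without symbols.

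Among the tested probes, 95 were higher and 40 were lower in the lnc-M2 siRNA samples than in the control siRNA samples (limma, Benjamini-Hochberg adjusted p under 0.05, n = 2 per group). The median change of the higher probes was 0.74 on the log2 scale, a 1.68-fold rise. The median of the lower probes was -0.80, a 1.75-fold fall. The changes ranged from 1.46-fold to 3.64-fold. Of the 135 called probes, 14 rose and 7 fell by at least 2-fold. In each of the 135, both knockdown arrays lay beyond both control arrays. With so few arrays, a call at this threshold requires such a separation, so it adds no support.

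The largest rise among the called probes was measured by probe A_23_P161428. Its log2 intensity was 7.14 ± 0.087 (SD, n = 2) in the knockdown samples and 5.40 ± 0.24 (SD, n = 2) in the control samples. The difference was 1.74 with a standard error of 0.13 (limma, adjusted p = 0.0128), or 3.35-fold. Both control arrays lay below 5.73, the brightness at the filter, so the fold rests on a control level not shown to be above background. Probe A_24_P303091 rose 2.32-fold among brighter transcripts, from 11.65 ± 0.070 to 12.86 ± 0.018 (limma, adjusted p = 0.0128). The largest fall among them was that of probe A_32_P6646. It went from 11.72 ± 0.048 in the control samples to 9.86 ± 0.052 in the knockdown samples. Its log2 change was -1.86 with a standard error of 0.081 (limma, adjusted p = 0.00432), or 3.64-fold. Probe A_24_P118953 fell 3.40-fold, from 6.92 ± 0.12 to 5.15 ± 0.18 (limma, adjusted p = 0.0128). Both of its knockdown arrays lay below 5.73, so its lower level is likewise not shown to be above background. These probes were chosen for large changes with non-overlapping groups, so their size relative to the SD of 2 arrays is partly set by that choice.

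**Figure D1:**
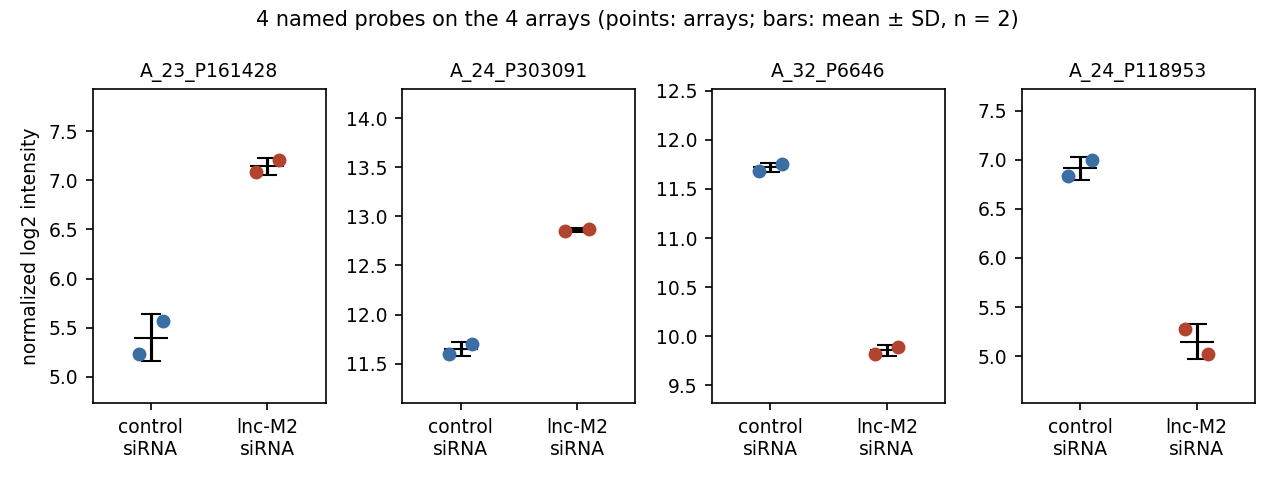
Normalized log2 intensity (vertical axis) of the 4 named probes in control siRNA and lnc-M2 siRNA samples; points are arrays and bars are the mean ± SD of 2 arrays. Both knockdown arrays lie above both control arrays for A_23_P161428 and A_24_P303091, and below them for A_32_P6646 and A_24_P118953.

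The called probes had means from 5.74 to 15.88 on the log2 scale, within a tested range that reached 18.72. Between the 40th and 60th percentiles of the mean, 57 of 8200 probes were called, with 41 higher and 16 lower. Between the 60th and 80th percentiles the count was 44, with 30 higher and 14 lower. Above the 80th percentile 34 were called, with 24 higher and 10 lower. The share called went from 0.70% of the dimmest of these 3 bins to 0.41% of the brightest. That share depends on the fit, since the 16400 probes of the upper 2 bins gave 78 calls here and 214 when fitted alone. At an unadjusted p under 0.05 there were 3184 probes, of which 1711 were higher and 1473 lower, against 1230 expected without any effect. The groups did not overlap in 44.7% of the tested probes, where chance gives 33.3% for 2 arrays against 2. Both reference figures are averages over arrays without any difference. How far so few arrays can stray from them was not measured, so neither excess is by itself a treatment effect.

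**Figure D2:**
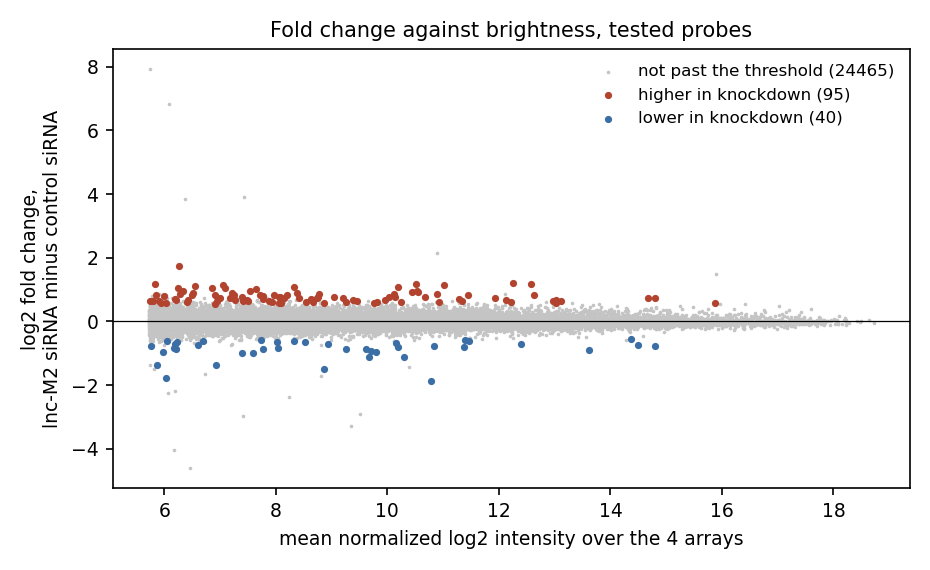
Log2 fold change of lnc-M2 siRNA over control siRNA (vertical axis) against the mean normalized log2 intensity of the 4 arrays (horizontal axis) for the 24600 tested probes; each point is a probe, with grey for those not past the threshold. The 95 probes higher and the 40 lower at the threshold have means between 5.74 and 15.88.

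The count of called probes depended on the settings. A trended robust prior in limma gave 500 calls, of which 344 were higher and 156 lower. With the replicate number as a block, limma called 0 of the 24600 tested probes. With the dim probes included, limma called 0 of 41000 probes, with 3500 at an unadjusted p under 0.05, while the fold changes themselves are the same in that fit. Leaving out 1 array gave 6 called probes (2 higher, 4 lower) without knockdown replicate 2 and 9 (1 higher, 8 lower) without control replicate 1. It gave 24 (11 higher, 13 lower) without control replicate 2 and 38 (23 higher, 15 lower) without knockdown replicate 1, so the majority of higher probes was present in 1 of these 4 fits.

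Control features were compared between the groups in the same way. The adenovirus E1A spike-ins are added at labelling in fixed amounts, so they carry technical spread only and not that between treated samples. Of these, 8 lay above the brightness filter, with means from 5.78 to 18.69. Their mean differences between the groups were at most 0.083 on the log2 scale. The spike-ins with means near 18.7 and 17.4 had an SD of 0 in 1 group, at or near the top of the scale. Over all 33 control features above the filter, the largest difference was 0.31. In a limma fit that kept them, 0 of the 33 passed the threshold and 0 had an unadjusted p under 0.05. Of the 24600 tested probes, 133 passed in that fit and 3186 had an unadjusted p under 0.05. At so low a share of calls, 0 of 33 past the threshold carries little information.

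Pairs of arrays were then compared within and between the groups. Among tested probes, knockdown and control arrays were at least 2-fold apart in 36 to 87 probes, depending on the pair. The 2 knockdown arrays differed by that much in 17 probes and the 2 control arrays in 20. Among dim probes the separation between groups was not detectable this way. There, 1177 to 1310 probes were 2-fold apart between a knockdown and a control array. The corresponding numbers were 1275 for the 2 knockdown arrays and 1206 for the 2 control arrays.

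**Figure D3:**
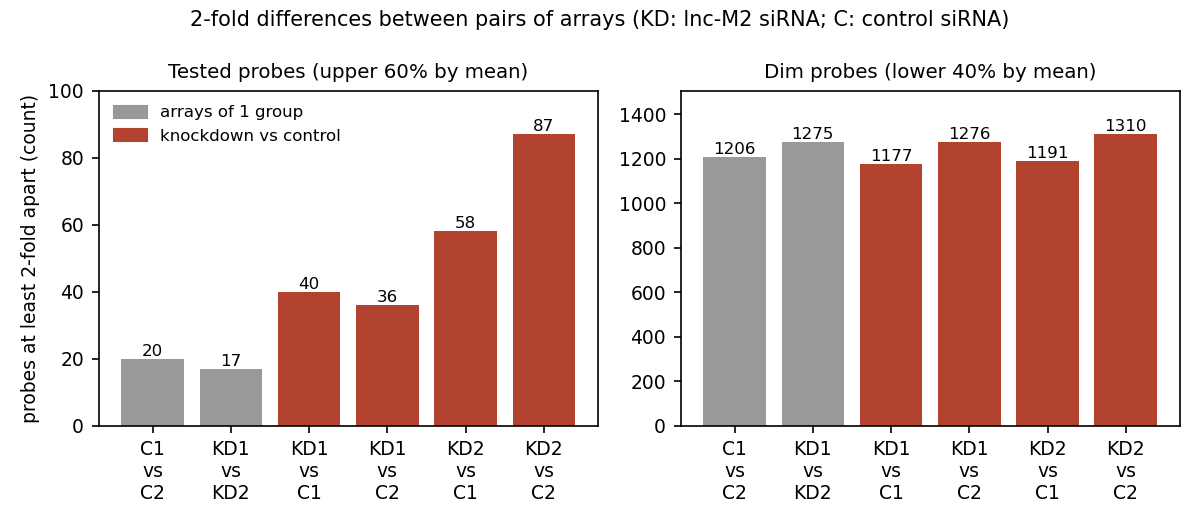
Number of probes at least 2-fold apart (vertical axis, linear) for each pair of arrays, among tested probes (left) and dim probes (right); grey bars are pairs within a group and red bars are knockdown against control. Tested probes gave 17 and 20 within groups against 36 to 87 between groups, and dim probes gave 1206 to 1275 within groups against 1177 to 1310 between groups.

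The authors' deposited table lists 539 probes for the replicate 1 pair, of which 233 were higher and 306 lower in the knockdown array. For the replicate 2 pair, the authors' deposited table lists 623 probes, with 411 higher and 212 lower. The share of higher probes was therefore 43.2% in the first list and 66.0% in the second. Dim probes made up 92.6% of the first list and 86.0% of the second. The lists in the authors' deposited table shared 96 probes, of which 35 were higher in both, 27 were lower in both and 34 went in opposite directions. Independent lists of these sizes drawn evenly from the 41000 probes would share 2.34, 1.58 and 4.27 such probes. Those figures are not what lists without a treatment difference would share, because noisy dim probes recur. Among dim probes, 299 were 2-fold apart in both within-group pairs, against 93.8 expected of independent pairs. Of these 299, 146 went the same way and 153 in opposite directions.

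The shared probes separated by brightness. All 19 shared probes that were tested moved the same way in both pairs, 11 higher and 8 lower, and 18 of these 19 passed the limma threshold. Those 18 passes are no independent support, since the probes were chosen for 2-fold differences on the same arrays. Of the 77 shared dim probes, 43 moved the same way and 34 in opposite directions. Of the 135 called probes, 29 stand in either list of the authors' deposited table and 106 in neither. The thresholds differ, since the lists hold probes 2-fold apart within a pair and the limma calls had no minimum fold. By group means, 21 of the 135 changed at least 2-fold. Every tested probe 2-fold apart in a same-numbered pair was listed, so the 106 were under 2-fold in both pairs.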

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

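Renormalizing the deposited values, or keeping control features, moved the count of 135 called probes little. The deposited arrays already shared practically the same sorted values, so another quantile normalization or median centring could hardly change it. Other ways to normalize the signals before deposit were not tested. limma called 134 probes after another quantile normalization, 133 after median centring, 124 after cyclic loess and 133 with control features kept, and each of these probes was among the 135. The last 2 of these settings were chosen after seeing the data. The count moved by over 1.5 times elsewhere. It was 0 without the filter on dim probes (smallest adjusted p 0.267), and 214 with the lower 60% left out, of which 78 were among the 135. It was 500 with a trended robust prior, which kept 134 of the 135. It was 315 at an adjusted p of 0.1, and 21 with a minimum of 2-fold. With the replicate number as a block it was 0, with 2717 probes at an unadjusted p under 0.05 and 1 residual degree of freedom. The main fit was planned without a block because no methods text says that the replicate number was used. The authors' lists do pair the arrays by number. Samples with the same number did not deviate together (r = -0.045 across tested probes). Leaving out 1 array gave 6 to 38 called probes, where the lone array of a group is assumed to vary like the other group. The cause of these changes was not tested. The 4 named probes passed the threshold in 31 of 42 values under alternatives. Their sign was mostly fixed by their choice for non-overlapping groups, so it says nothing about stability. One probe per gene, the mean of a gene's probes and the gene list tests were not run, because no probe could be matched to a gene. Signal over background could not be judged, so the filter on mean intensity stands in for detection.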

Other observations

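The tests on pairs that share no array, on brightness bins, on dim probes and on other splits were chosen after the result was seen.

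Differences between the groups among tested probes recurred in pairs that share no array. Of the probes 2-fold apart in both same-numbered pairs, 19 of 19 went the same way, and with crossed numbers 17 of 18 did. These 19 are the tested probes that the authors' 2 lists share. A deviation of 1 array would give about equal numbers of both directions, which the 19 did not show. Yet 1 array lies in only 1 of the 2 pairs. Choosing probes 2-fold apart in both thus largely excludes that cause beforehand, and says nothing of the other called probes. In the 2 within-group pairs, 2 of 2 such probes went the same way, too few to compare. Across all tested probes, differences correlated at r = 0.213 between same-numbered pairs and 0.257 between crossed pairs. Between the within-group pairs the correlation was -0.045. Over 20 bins of brightness, the median fold change of all tested probes was at most 0.021 in size on the log2 scale. The smallest change of a called probe was 0.55. Arrays with practically the same sorted values leave little room for an intensity-dependent offset. The bin medians were therefore small by construction and are no test of that cause. The 4 arrays allow only 3 splits, too few for a share under 0.05: the real one, 1 of the 3, gave 135 called probes and the highest of the others gave 0. Each other split mixes the groups, so any group difference adds to its spread. Its 0 is therefore no measure of how many calls arise without an effect, to set against the 135 called probes. A response to loss of lnc-M2, an off-target effect of the siRNA and a difference in handling between the groups may each account for these probes, and no test here separates them.

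The 2-fold differences of dim probes within a pair may mostly reflect the spread between any 2 arrays. The 4 knockdown-control pairs held on average 0.998 times as many 2-fold dim probes as the 2 within-group pairs, 1238.5 against 1240.5. Of the 294 dim probes 2-fold apart in both same-numbered pairs, 48.0% went the same way, which argues against a difference shared by both knockdown arrays for these probes as a set. These counts include probes the authors did not list; of the 77 dim probes in both of the authors' deposited lists, 43 went the same way and 34 did not. Single dim transcripts that respond stay open.

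The replicate 2 pair differed more than the replicate 1 pair, with 87 against 40 tested probes at least 2-fold apart. Of the 200 tested probes with the largest difference in the replicate 1 pair, 85.5% went the same way in the replicate 2 pair. Of the 200 largest in the replicate 2 pair, 54.5% went the same way in the replicate 1 pair. With crossed numbers, the 200 largest differences of knockdown replicate 2 against control replicate 1 gave 80.5%. The 3 pairs that hold knockdown replicate 2 had differences whose median absolute deviation, scaled to an SD, was 0.159, 0.191 and 0.202 on the log2 scale, and the other 3 pairs had 0.117 to 0.157. No explanation of this difference was tested.

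In 15 probes, 1 array lay over 5 log2 units (32-fold) above the other 3, and in 0 probes 1 array lay that far below. Control replicate 1 held 9 of these probes, knockdown replicate 2 held 5, knockdown replicate 1 held 1 and control replicate 2 held 0. The largest gap was 16.18 log2 units. All 15 stand in the authors' deposited lists, 10 for the replicate 1 pair and 5 for the replicate 2 pair. That 0 of the 15 passed the limma threshold follows from their choice, since 1 array lies far from its own replicate.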
